A study of Homo sapiens with 6 samples.

How the data were processed

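RNA for 6 libraries of the IOMM-Lee meningioma cell line, 3 labelled control and 3 labelled KMT2C knockdown, was extracted with TRIzol and made into libraries with the VAHTS Universal V6 kit, per the labels; whether the libraries are stranded is not stated. Per the submitters' processing notes, reads were processed with fastp, HISAT2, HTSeq and DESeq2 in R 3.2.0 against GRCh38.p13, with no settings given. A single table of 17480 genes, 14068 protein-coding and 3412 non-coding, was deposited. It holds only genes with a mean of about 1 normalized read or more.

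The per-library columns hold FPKM that the authors computed as reads assigned to each gene scaled by gene length and library size. The table's group means are a signal that the authors computed as normalized counts, the mean over libraries of reads divided by DESeq2 size factors. The deposited fold change is a ratio of knockdown to control, and the deposited log2 fold change is its log2. The deposited p-value and q-value come from the authors' DESeq2 comparison, and the q-value equals the Benjamini-Hochberg adjustment of the p-value over the listed genes.

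Whole read counts were recovered from the FPKM values, gene lengths and group means: 100% of 104880 values lay within 0.001 reads of a whole number, with a largest deviation of 1.3e-09. Depth was 36.1 to 40.7 M reads per library. Intervals and floors cover counting error only, since reads without molecular identifiers are not independent molecules. Ratios against 1 to 3 control reads carry an exact 95% interval, and ratios against 0 reads are lower bounds against a floor of 3 reads over the group.

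The plan named a quasi-likelihood test for a table of counts and limma-trend for a table that holds only FPKM. The table holds FPKM, so limma 3.58.1 in R 4.3.3 was run on log2(FPKM + 1) of genes with a mean of at least 1 FPKM, with Benjamini-Hochberg adjustment and a threshold of 0.05. No replicate block was used, since the labels do not say that a number marks a shared culture. KMT2C was also tested with an exact permutation test on log2 CPM (read counts scaled to library size). The replicates are not stated to be separate cultures, so the p-values measure only the spread between these samples. Limma camera tested lists with at least 5 tested members, with a preset correlation of 0.01 and again with an estimated one, and fry was run beside it. The plan named log2 CPM for the camera tests, but they were run on log2(FPKM + 1), as the main fit was. Per the plan, counts of list members are given over all tested genes and adjusted over the list alone.

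Named genes were KMT2C and the members of its complexes that passed; the 12 largest rises and 12 largest falls at an adjusted p below 0.05 with a symbol, a mean of at least 5 CPM and no overlap between groups; the 6 smallest adjusted p; and up to 4 members per list with the smallest adjusted p (8 for Hippo genes and YAP/TAZ targets). The text gives examples from these, and 5 further list members (CCN1, GADD45A, NUAK2, MAP4K4 and IFIT5) chosen after their values were seen. Other genes chosen after their values were seen are marked where they appear. Gene positions come from GENCODE 29, matched by Entrez number for 15637 genes.

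Alternatives were median-of-ratios and upper-quartile scaling, no filter, a filter of 5 CPM in at least 3 libraries, a replicate block, limma-voom on the recovered reads, a pseudocount of 0.1, leaving out each library and the authors' deposited Wald test. Removing the gene length or GC-content trend from each library was added after seeing the data. Other splits of the 6 libraries into 3 and 3 were fitted in the same way. The pipeline was tested on simulated data with 50 changed genes at each fold size and a dispersion of 0.015 in both groups. There it recovered 60.4% of genes changed 1.5-fold and 100% of genes changed 2-fold. It called 11 unchanged genes, with 10517 genes tested in all. In the real data 31.1% of genes were called. Their median dispersion was 0.00374 in the controls and 0.0134 in the knockdown-labelled libraries, so the simulated rates need not carry over. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for tables and figures. XIST and Y-linked genes were not examined.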

Results

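RNA sequencing was carried out on 6 libraries of IOMM-Lee cells, a human cell line established from a malignant meningioma, a tumour of the membranes that cover the brain. By their labels, 3 libraries came from control cells and 3 from cells with knockdown of KMT2C, which encodes a histone H3 lysine 4 methyltransferase of the enhancer-associated complexes. The single comparison of the design asked how lowering KMT2C changes gene expression, and the series title places it in the context of H3K27 acetylation and the Hippo pathway, a kinase cascade that restrains the coactivators YAP and TAZ. The control libraries held 36.1, 40.7 and 40.0 M reads in the 17480 listed genes, and the knockdown-labelled libraries held 38.6, 37.7 and 38.0 M reads. Of the listed genes, 10523 had a mean of at least 1 FPKM (reads scaled by gene length and library size) and were tested with limma. Values are means ± SD with n = 3 libraries per group unless stated otherwise, and a gene is said to have risen or fallen when its limma adjusted p was below 0.05. Unless stated otherwise, log2 changes are of FPKM + 1 and fold values are ratios of mean FPKM. At low levels the log2 changes are therefore smaller than the fold values imply.

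KMT2C itself (Entrez 58508, GRCh38 chromosome 7, 152134922 to 152436005) averaged 1.60 ± 0.496 FPKM in the control libraries and 1.027 ± 0.275 FPKM in the knockdown-labelled libraries (SD, n = 3). The control libraries had 2.01, 1.75 and 1.05 FPKM, from 1279, 1249 and 741 reads. The knockdown-labelled libraries had 1.26, 0.725 and 1.09 FPKM, from 859, 481 and 732 reads. The groups therefore overlapped, because the library labelled control replicate 3 lay below the libraries labelled knockdown replicate 1 and knockdown replicate 3. The log2 change was -0.35 with a standard error of 0.15, a 95% confidence interval of -0.67 to -0.03 and a limma adjusted p of 0.0854. With 0.1 FPKM added in place of 1 the log2 change was -0.58 (limma adjusted p 0.0949). On log2 CPM (read counts scaled to library size) the difference was -0.63, with a two-sided exact permutation p of 0.3, where 0.1 is the smallest p that 3 against 3 libraries allow. The authors' deposited table gives KMT2C a log2 fold change of -0.63 with a q-value of 0.0187. Without the library labelled control replicate 3 the limma adjusted p was 0.0263 at a log2 change of -0.51. KMT2C also passed with the stricter filter (limma adjusted p 0.0429) and with limma-voom on the recovered reads (0.0225, at a log2 change of -0.61), and its adjusted p was 0.063 to 0.322 in the settings that kept it short of the threshold. The libraries are therefore named by their labels throughout, since KMT2C mRNA did not separate the groups.

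**Figure D1:**
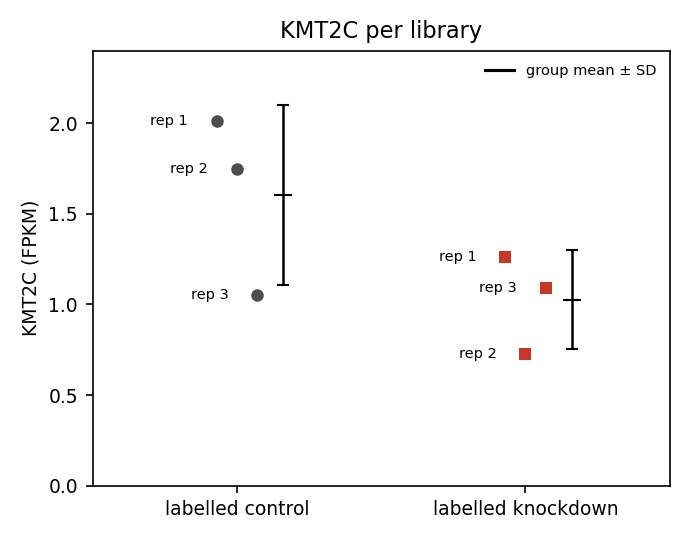
KMT2C level in FPKM (vertical axis) in each of the 6 libraries, by labelled group (horizontal axis), with each group's mean and SD as a bar beside the points. The library labelled control replicate 3, at 1.05 FPKM, lies below 2 of the 3 knockdown-labelled libraries.

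Of the 17 tested members of the KMT2 methyltransferase complexes, 1 rose and 1 fell over all genes tested, and 0 rose and 1 fell when adjusted over the list alone. WDR5, the core subunit shared by these complexes, fell from 26.8 ± 0.841 to 19.9 ± 2.72 FPKM (limma adjusted p 0.00782). KMT2B rose from 5.69 ± 1.27 to 7.61 ± 0.453 FPKM (limma adjusted p 0.0447), and its adjusted p was 0.229 without control replicate 3, 0.0898 without knockdown replicate 2 and 0.117 without knockdown replicate 3, 0.128 with no filter on low values and 0.0852 with the GC-content trend removed. The list as a whole had a limma camera adjusted p of 0.573. A list of writers, readers and erasers of H3K27 acetylation had 15 tested genes. Of these, 1 rose and 2 fell, and 1 rose and 1 fell when adjusted over the list alone. The limma camera adjusted p was 0.576. The list also holds EZH2, EED and SUZ12, genes of H3K27 methylation, so its counts are not of acetylation genes alone. HDAC5, a histone deacetylase, rose from 2.61 ± 0.147 to 5.68 ± 1.39 FPKM, and HDAC1 fell from 81.4 ± 1.16 to 63.9 ± 6.87 FPKM. The other fall was EZH2, the H3K27 methyltransferase (limma adjusted p 0.0441), which passed without knockdown replicate 1 but with no other library left out, where its adjusted p lay between 0.0983 and 0.174, and which had 0.116 with no filter on low values, 0.0667 with upper-quartile factors and 0.0657 with the gene length trend removed.

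Across the transcriptome, 3268 of the 10523 tested genes changed, which is 31.1%. Of these, 1499 were higher and 1769 were lower in the knockdown-labelled libraries. At a change of at least 2-fold in FPKM + 1, 223 genes passed, of which 155 were higher and 68 lower. HDAC5, for example, rose at a ratio of mean FPKM of 2.18 but is not counted, at a log2 change of 0.87. The median log2 change over all tested genes was -0.04, and the balance of directions depended on the scale: with upper-quartile factors 1835 of 3154 genes were higher, which is 58.2% against 45.9% on the deposited scale. The count at 2-fold was 441 with limma-voom on the recovered reads and 411 with a pseudocount of 0.1. Among the called genes, 3136 had all 3 knockdown-labelled values outside the range of the controls, as had 44.7% of all tested genes, where chance gives 10%. The authors' deposited values include 4189 of 17480 genes with a q-value below 0.05, 2195 of them higher and 1994 lower. Of the genes called here, 3046 were also among those 4189, all in the same direction. Of 33 gene lists fixed before the data were examined, 29 had at least 5 tested members, and limma camera with a preset correlation called 12 of them, 6 up and 6 down. None of the 12 was called with a correlation estimated per list, where limma camera called 0 of 29 lists. Limma fry, which tests whether a list's genes move on balance 1 way and does not compare them with other genes, called 13. Under fry the adjusted p was 0.105 for homologous recombination, MYC and oxidative phosphorylation genes and 0.165 for mitochondrially encoded mRNAs, which camera called. It was 0.0101 for TGF-beta response, 0.00834 for Wnt, 0.0137 for immediate-early, 0.00163 for cholesterol synthesis and 0.00138 for meningioma aggressiveness genes, which camera did not call.

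The largest rises were in chemokine genes and interferon-stimulated genes. CXCL10, a chemokine that attracts T cells (chromosome 4, 76021117 to 76023497), rose from 0.0362 ± 0.0439 FPKM, on 5 reads in the 3 control libraries, to 58.3 ± 25.01 FPKM. CXCL11, its neighbour on chromosome 4 (76033682 to 76041415), reached 26.3 ± 9.04 FPKM from 0.0550 FPKM. CCL5 (chromosome 17, 35871491 to 35880793) rose from 0.0399 ± 0.0386 to 52.97 ± 26.2 FPKM, on 6 control reads and 7840 knockdown reads. CCL3L3 (chromosome 17, 36194869 to 36196758) had 2 control reads against 8815 knockdown reads, a ratio of 4500 with a 95% counting interval of 1250 to 37200. CCL4L2 (chromosome 17, 36210924 to 36212878) had 1 control read against 2269, a ratio of 2320 with an interval of 415 to 91500. CCL3L3 and CCL4L2 have near-identical copies, CCL3 and CCL4, and the reads of such copies cannot be fully assigned to 1 of them. OASL (chromosome 12, 121019111 to 121039242), an interferon-induced antiviral gene, rose 90.7-fold from 1.19 ± 0.162 to 108 ± 28.6 FPKM, with a log2 change of 5.61, a standard error of 0.15 and a limma adjusted p of 3.115e-13. RSAD2, which encodes the antiviral protein viperin, rose 128-fold to 33.0 ± 8.15 FPKM. In the IFIT cluster on chromosome 10 (89283694 to 89406486), IFIT2 rose 35.0-fold, IFIT1 18.3-fold and IFIT3 from 5.63 ± 0.363 to 115 ± 26.9 FPKM. The 12 largest rises also included VGF, a secreted neuropeptide precursor, at 32.2-fold, and KRT17, a keratin, at 23.8-fold. In each of these 12 genes all 3 knockdown-labelled libraries lay above all 3 controls, which the rule for naming them required.

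**Figure D2:**
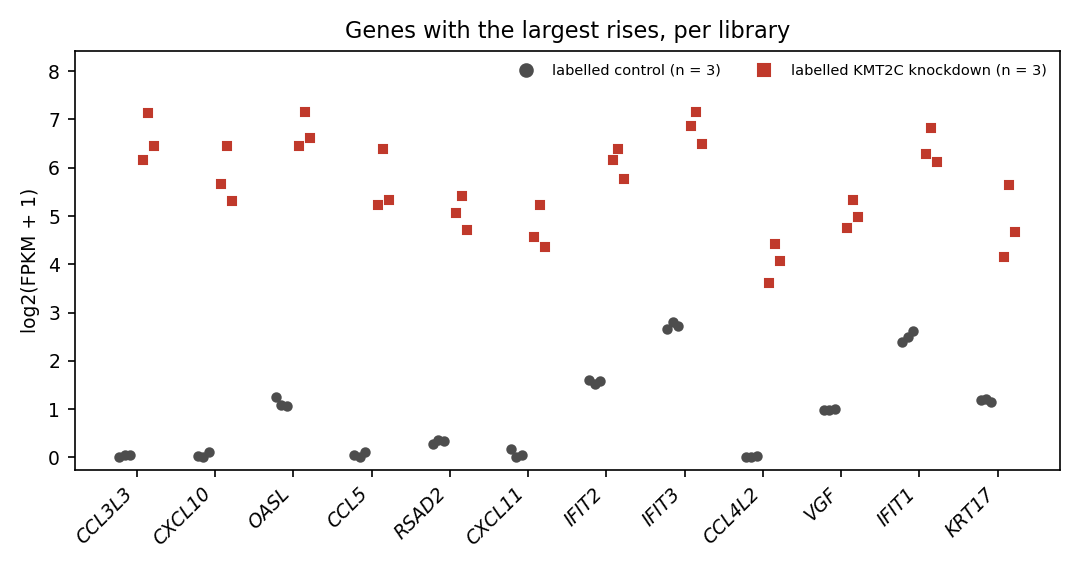
Levels of the 12 genes with the largest rises, as log2(FPKM + 1) (vertical axis), with 1 point per library and the 3 control and 3 knockdown-labelled libraries shown side by side for each gene (horizontal axis). The genes were chosen with no overlap between the groups, so every knockdown-labelled point lies above every control point. OASL was at 1.19 FPKM in controls and 108 FPKM in the knockdown-labelled libraries.

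Of the 29 tested interferon-stimulated genes, 22 rose and 1 fell, and 25 rose and 1 fell when adjusted over the list alone. The fall was IFIT5, chosen after its values were seen, at a limma adjusted p of 0.034. It passed only with all libraries or without knockdown replicate 1, with an adjusted p of 0.0536 to 0.143 when any other library was left out, 0.0533 with upper-quartile factors and 0.097 with no filter on low values. The list had a limma camera adjusted p of 3.1e-20 and a median log2 change of 0.77. The adjusted p was 0.499 with an estimated correlation. NF-kB and inflammatory cytokine genes moved the same way, with 12 of 17 rising and 0 falling, and 13 rising when adjusted over the list alone (limma camera adjusted p 2.64e-10; adjusted p = 0.499 with an estimated correlation). NFKBIA, the inhibitor that NF-kB itself induces, rose from 21.7 ± 0.326 to 76.7 ± 27.4 FPKM, and ICAM1, an adhesion molecule, rose from 8.97 to 27.7 FPKM. Of 17 antigen presentation genes, 13 rose and 0 fell, as they did when adjusted over the list alone (limma camera adjusted p 2.64e-10; adjusted p = 0.526 with an estimated correlation). CD74, the invariant chain of MHC class II, rose from 0.967 ± 0.210 to 25.1 ± 14.5 FPKM. HLA-DRA rose 30.2-fold to 6.50 ± 2.31 FPKM and HLA-DMA rose to 8.78 ± 2.18 FPKM. HLA-DRB1, which shares sequence with other HLA-DRB genes, reached 9.98 ± 4.29 FPKM. The macrophage marker CD68, the only leukocyte marker with enough signal to test, rose from 107.5 ± 2.34 to 145.1 ± 13.6 FPKM. In the same comparison 20 of 30 ribosomal protein genes rose and 9 of 13 mitochondrially encoded mRNAs fell (limma camera adjusted p 2.57e-07 and 9.65e-04; adjusted p = 0.623 and 0.624 with an estimated correlation). Between 4 and 8 ribosomal protein genes rose without control replicate 1, control replicate 2, knockdown replicate 2 or knockdown replicate 3, and 6 with no filter on low values.

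Genes induced by YAP and TAZ were mostly lower in the knockdown-labelled libraries. Of 26 tested YAP/TAZ target genes, 17 fell and 3 rose, and 19 fell and 3 rose when adjusted over the list alone. The limma camera adjusted p was 6.92e-08, and the adjusted p was 0.422 with an estimated correlation. ANKRD1 (chromosome 10, 90912096 to 90921276), a classical YAP target, fell from 28.5 ± 2.22 FPKM in controls, 7.66-fold the knockdown level, at a limma adjusted p of 2.554e-11. CCN2, which encodes connective tissue growth factor, fell from 84.0 ± 4.27 to 29.5 ± 5.09 FPKM. THBS1, which encodes thrombospondin, was 5.90-fold and IGFBP3 5.41-fold higher in the controls. The 3 target genes that rose were chosen after their values were seen. CCN1 rose from 599 ± 0.993 to 856 ± 232 FPKM, GADD45A from 47.7 ± 2.48 to 77.5 ± 23.3 FPKM, and NUAK2 from 4.72 ± 0.216 to 8.54 ± 3.002 FPKM. The rise of CCN1 (limma adjusted p 0.0128) had an adjusted p of 0.0516 without control replicate 3 and 0.0525 without knockdown replicate 2. With no filter on low values the adjusted p was 0.0997 for CCN1, 0.0572 for GADD45A and 0.0566 for NUAK2. Of 6 tested YAP, TAZ and TEAD factors, 1 rose and 2 fell, also when adjusted over the list alone, with a limma camera adjusted p of 0.691. TEAD1 fell from 15.7 ± 2.24 to 9.40 ± 1.84 FPKM and TEAD3 rose from 7.88 ± 0.505 to 11.4 ± 1.80 FPKM. YAP1 fell from 24.0 ± 1.41 to 18.3 ± 1.90 FPKM (limma adjusted p 0.0116), with an adjusted p of 0.0739 without control replicate 1.

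Of 23 tested core components and regulators of the Hippo pathway, 10 fell, 1 rose and 12 did not pass, and 12 fell and 1 rose when adjusted over the list alone. NF2 (chromosome 22, 29603556 to 29698598), the meningioma tumour suppressor that activates the Hippo kinases, fell from 20.9 ± 0.167 to 13.3 ± 1.33 FPKM, with a log2 change of -0.62 and a limma adjusted p of 3.713e-04. WWC3 fell from 6.19 ± 0.470 to 2.83 ± 0.524 FPKM and FRMD6 from 23.4 ± 0.861 to 13.9 ± 2.15 FPKM. LATS2, a Hippo kinase, fell from 13.4 ± 1.30 to 9.71 ± 0.734 FPKM (limma adjusted p 0.00944), but its adjusted p was 0.0607 without control replicate 1 and 0.0549 without control replicate 2. AMOTL2 also fell (limma adjusted p 0.00978, and 0.0673 without control replicate 2). LATS2 and AMOTL2 are on the YAP/TAZ target list too. The rise was MAP4K4, a kinase upstream of LATS, chosen after its values were seen, from 21.6 ± 2.07 to 27.6 ± 3.68 FPKM (limma adjusted p 0.0343). MAP4K4 passed without control replicate 1 or knockdown replicate 3, and its adjusted p lay between 0.0666 and 0.147 without any other library, and was 0.091 with no filter on low values. The limma camera adjusted p of the list was 0.00745, the adjusted p was 0.623 with an estimated correlation, and it was 0.0506 without knockdown replicate 3. The number of falls was 5 without control replicate 1, 4 without control replicate 2 and 6 without knockdown replicate 2, and it was 6 of 27 with no filter on low values. The median log2 change between the groups was 0.10 in the shortest of 5 length classes and -0.10 in the longest class, where knockdown replicates 2 and 3 and control replicate 3 were low and knockdown replicate 1, at 0.021, was not.

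**Figure D3:**
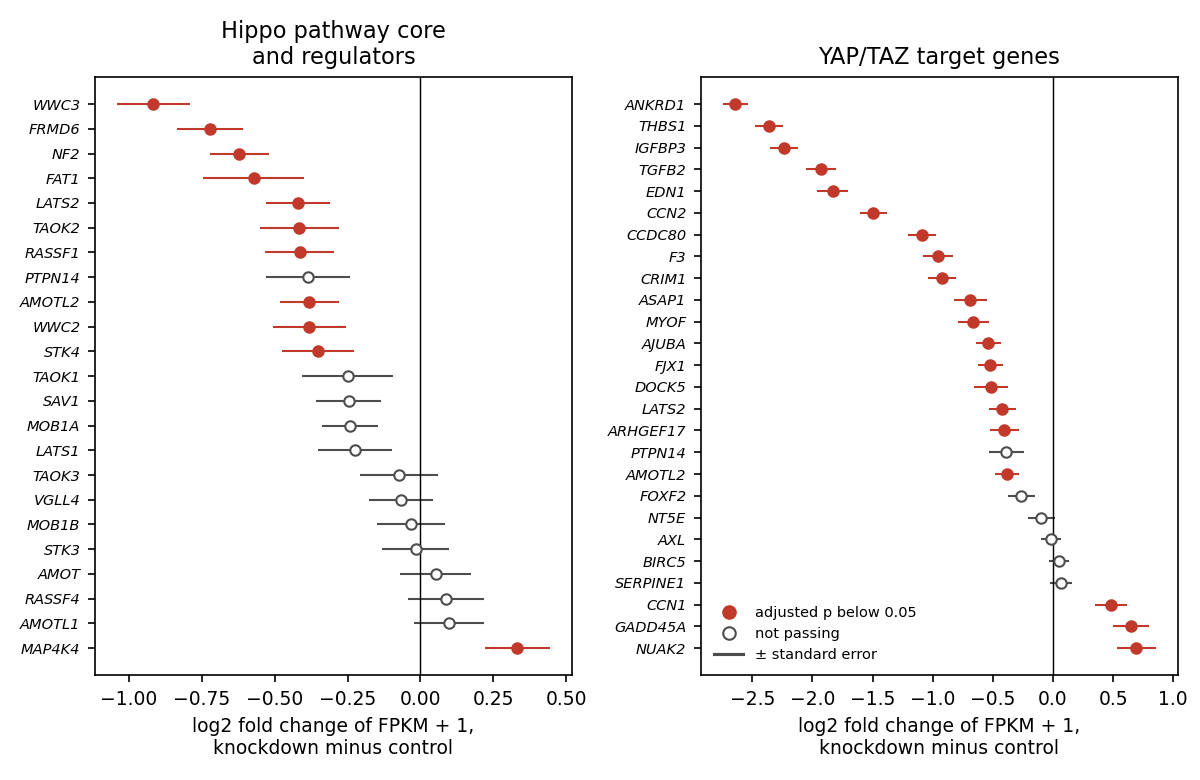
Log2 change of FPKM + 1, knockdown minus control (horizontal axis), of each tested Hippo pathway gene (left) and YAP/TAZ target gene (right), with standard errors; filled points passed at an adjusted p below 0.05 over all tested genes. Of 23 Hippo genes 10 fell and 1 rose, and of 26 target genes 17 fell and 3 rose.

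TAGLN, the actin-binding protein transgelin (chromosome 11, 117199321 to 117204782), had the largest fall, from 60.1 ± 3.32 to 4.602 ± 0.861 FPKM, with a log2 change of -3.46 and a limma adjusted p of 3.115e-12. MYL9, the light chain of contractile myosin, fell from 11.8 ± 0.421 to 2.16 ± 0.256 FPKM. Secreted growth factor and signalling genes were also among the 12 largest falls: TGFB2 fell from 8.29 ± 0.950 to 1.44 ± 0.245 FPKM, WNT5B from 6.94 ± 0.465 FPKM, and EDN1, the endothelin precursor, to 2.70 ± 0.505 FPKM. TNFRSF11B, the decoy receptor osteoprotegerin, fell from 6.96 ± 0.395 FPKM and ITGB2, an integrin chain, from 11.4 ± 0.762 to 2.38 ± 0.255 FPKM. TGFB2 and EDN1 are also on the YAP/TAZ target list, as are ANKRD1, THBS1 and IGFBP3 among the 12, and the remaining 2 were CPA4, a carboxypeptidase, at a log2 change of -2.06, and IGFBP7, a secreted binding protein, at -1.80. Of 16 TGF-beta response genes, 7 fell and 4 rose, also when adjusted over the list alone. Their limma camera adjusted p was 0.15, but 0.0326 without knockdown replicate 2, 0.023 with no filter on low values and 0.0263 with the stricter filter. BAMBI, a pseudoreceptor that dampens TGF-beta signals, rose from 1.74 ± 0.276 to 5.09 ± 2.50 FPKM. Among collagens and extracellular matrix genes, 6 rose and 7 fell of 18, and 6 rose and 9 fell when adjusted over the list alone, with a limma camera adjusted p of 0.987, a median of -0.17 and a mean of 0.09 on the log2 scale, which differ in sign. LUM, the proteoglycan lumican, rose 8.99-fold and LOXL2, a collagen cross-linking enzyme, fell from 101.4 ± 7.93 to 48.8 ± 5.67 FPKM. Of 18 epithelial-mesenchymal transition genes, 7 rose and 3 fell, also when adjusted over the list alone (limma camera adjusted p 0.16). The list mixes epithelial genes such as CLDN1 with mesenchymal genes such as TNC, so its counts and test give no direction of the transition. CLDN1, a tight-junction claudin, fell from 12.7 ± 0.532 to 4.78 ± 0.111 FPKM, and TNC, the matrix protein tenascin C, rose from 9.41 ± 1.86 to 25.4 ± 1.62 FPKM.

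**Figure D4:**
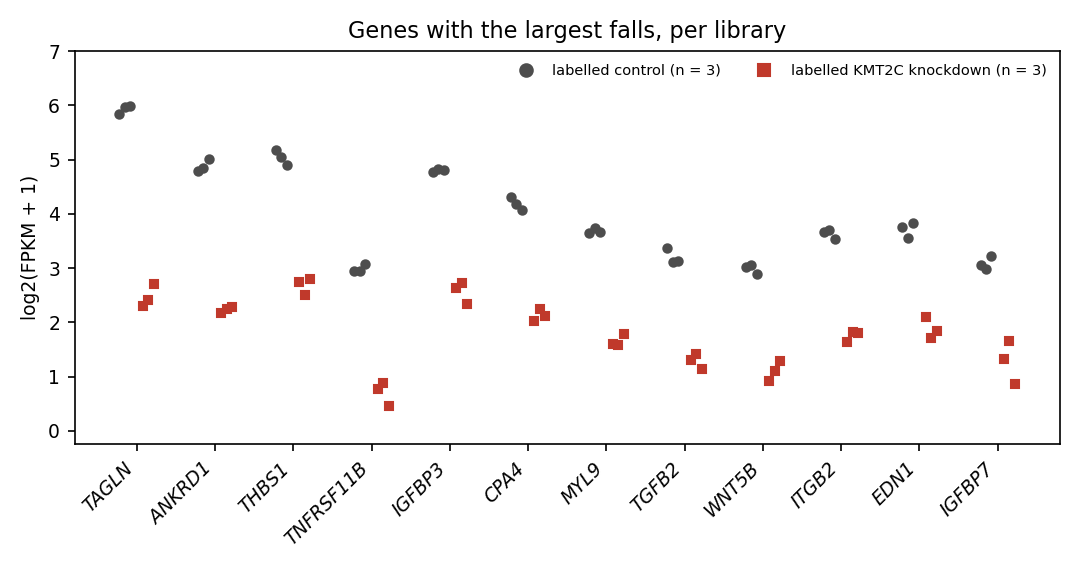
Levels of the 12 genes with the largest falls, as log2(FPKM + 1) (vertical axis), with 1 point per library and the 3 control and 3 knockdown-labelled libraries shown side by side for each gene (horizontal axis). The genes were chosen with no overlap between the groups, so every knockdown-labelled point lies below every control point. TAGLN was at 60.1 FPKM in controls and 4.602 FPKM in the knockdown-labelled libraries.

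Of 31 G1/S cell cycle genes, 17 fell and 1 rose, and 22 fell and 1 rose when adjusted over the list alone (limma camera adjusted p 8.59e-07; adjusted p = 0.623 with an estimated correlation). UHRF1, which maintains DNA methylation at replication, fell from 33.2 ± 2.69 to 18.7 ± 2.61 FPKM and CDC6, a replication licensing factor, from 20.3 ± 1.07 to 11.3 ± 2.18 FPKM. CDT1, another licensing factor, rose from 38.1 ± 1.61 to 56.5 ± 4.77 FPKM. Among 32 G2/M genes 6 fell and 0 rose, also when adjusted over the list alone, with a limma camera adjusted p of 0.15, which was 0.0313 with no filter on low values. PLK1, a mitotic kinase, fell from 133.7 ± 4.46 to 103.7 ± 6.21 FPKM. Of 22 homologous recombination and DNA damage response genes, 8 fell and 1 rose, and 10 fell and 1 rose when adjusted over the list alone (limma camera adjusted p 0.0189; adjusted p = 0.631 with an estimated correlation, 0.0696 without knockdown replicate 3 and 0.0602 with the gene length trend removed). XRCC3 fell from 18.1 ± 1.18 to 12.1 ± 1.40 FPKM and BARD1, the partner of BRCA1, from 5.41 ± 0.299 to 3.27 ± 0.915 FPKM. Of 21 p53 target genes 5 rose and 5 fell, and 6 rose and 5 fell when adjusted over the list alone (limma camera adjusted p 0.241). CDKN1A, which encodes the cell cycle inhibitor p21, rose from 97.3 ± 4.58 to 189.6 ± 80.6 FPKM, at an adjusted p of 0.0562 with no filter on low values, and MDM2 fell from 12.8 ± 0.715 to 8.27 ± 1.02 FPKM. Of 22 MYC and ribosome biogenesis genes, 9 fell and 2 rose, and 11 fell and 2 rose when adjusted over the list alone (limma camera adjusted p 0.0218; adjusted p = 0.631 with an estimated correlation). That call was lost without knockdown replicate 1, at 0.0596, and without knockdown replicate 2, at 0.0551. MYC itself rose from 73.6 ± 0.333 to 98.0 ± 2.99 FPKM.

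Among 21 immediate-early and MAPK feedback genes, 9 rose and 4 fell, and 9 rose and 8 fell when adjusted over the list alone (limma camera adjusted p 0.15). EGR1 rose 10.9-fold to 15.6 ± 5.74 FPKM, JUNB rose from 10.7 ± 0.753 to 43.2 ± 12.9 FPKM, and JUN fell from 76.2 ± 4.23 to 48.4 ± 3.86 FPKM. Of 23 unfolded protein and integrated stress response genes, 7 rose and 6 fell, and 8 rose and 6 fell when adjusted over the list alone. DDIT3, a stress-induced transcription factor, rose from 5.10 ± 0.127 to 14.4 ± 2.42 FPKM. The limma camera adjusted p of that list was 0.546, with a median of -0.005 and a mean of 0.03, which differ in sign. Among 27 hypoxia and glycolysis genes 9 rose and 4 fell, also when adjusted over the list alone (limma camera adjusted p 0.15), and CA9, a carbonic anhydrase, rose from 57.1 ± 6.01 to 126.9 ± 35.2 FPKM. Among 23 cholesterol synthesis genes 1 rose and 6 fell, also when adjusted over the list alone (limma camera adjusted p 0.15, and 0.0313 with no filter on low values). Of 9 Wnt and beta-catenin targets 3 rose and 3 fell, also when adjusted over the list alone (limma camera adjusted p 0.691), with CCND1, which encodes cyclin D1, falling from 70.1 ± 3.44 to 34.5 ± 5.64 FPKM. Of 6 Notch pathway genes 0 rose and 1 fell, and 0 changed when adjusted over the list alone (limma camera adjusted p 0.691). That fall was LFNG, from 3.62 ± 0.465 to 2.57 ± 0.626 FPKM (limma adjusted p 0.0482), whose adjusted p lay between 0.0504 and 0.189 without any library other than knockdown replicate 3, and was 0.139 with no filter on low values. It was 0.0704 with upper-quartile factors, 0.0504 with a pseudocount of 0.1, 0.0524 with the gene length trend removed and 0.056 in the authors' deposited Wald test of LFNG. Of 14 HOX genes 1 rose and 1 fell, also when adjusted over the list alone (limma camera adjusted p 0.785). These were HOXB9, with a limma adjusted p of 0.0153, and HOXA10, at 0.0114. HOXB9 had an adjusted p of 0.0647 without control replicate 2 and 0.0737 without control replicate 3, and HOXA10 had 0.0786 without control replicate 1 and 0.0526 with no filter on low values.

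Of 10 meningioma and arachnoid markers, 3 rose and 2 fell, also when adjusted over the list alone, with a limma camera adjusted p of 0.573, a median of -0.05 and a mean of 0.14, which differ in sign. CRABP2, a retinoic acid binding protein, rose from 13.3 ± 2.04 to 38.6 ± 4.59 FPKM, and KLF4 rose from 4.63 ± 0.403 to 10.2 ± 3.36 FPKM. Of 22 meningioma aggressiveness genes, 1 rose and 6 fell, also when adjusted over the list alone, with a limma camera adjusted p of 0.366, a median of 0.01 and a mean of -0.22, which differ in sign. TERT, the telomerase catalytic subunit, fell from 8.19 ± 0.787 to 3.73 ± 0.548 FPKM and MYBL2 from 109.8 ± 4.01 to 75.9 ± 10.6 FPKM.

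Ribosomal protein genes and mitochondrially encoded mRNAs, lists set as checks of RNA quality, also differed between the groups with the preset correlation. So did replication-dependent histone genes and nuclear-encoded oxidative phosphorylation genes. RNA quality itself was not tested. Of 30 ribosomal protein genes 20 rose and 0 fell, and 23 rose when adjusted over the list alone (limma camera adjusted p 2.57e-07; adjusted p = 0.623 with an estimated correlation). The number of rises depended on single libraries, at 4 without control replicate 1, 7 without control replicate 2, 6 without knockdown replicate 2 and 8 without knockdown replicate 3, and it was 6 with no filter on low values. RPLP0 rose from 3633 ± 229 to 5083 ± 472 FPKM. Of 13 mitochondrially encoded mRNAs 0 rose and 9 fell, and 10 fell when adjusted over the list alone (limma camera adjusted p 9.65e-04; adjusted p = 0.624 with an estimated correlation), with CYTB falling from 1832 ± 132 to 981 ± 375 FPKM. Of 15 replication-dependent histone genes, whose mRNAs mostly lack poly(A) tails, 6 rose and 0 fell, and 9 rose when adjusted over the list alone (limma camera adjusted p 9.65e-04; adjusted p = 0.526 with an estimated correlation). H1-2 rose from 92.2 ± 7.83 to 238.6 ± 53.6 FPKM. Of 23 nuclear-encoded oxidative phosphorylation genes 2 rose and 0 fell, and 1 rose when adjusted over the list alone (limma camera adjusted p 0.0114; adjusted p = 0.631 with an estimated correlation). COX6C rose from 106.8 ± 7.61 to 153.5 ± 4.81 FPKM. That list's adjusted p was 0.0794 without control replicate 1, 0.0558 without control replicate 2, 0.0506 without knockdown replicate 3 and 0.292 with the gene length trend removed.

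Markers of other cell types were too few for a list test. The only tested leukocyte marker, CD68, rose, as it did when adjusted over the list alone. Of 2 endothelial and pericyte markers, TEK fell from 1.93 ± 0.247 to 0.675 ± 0.203 FPKM and TIE1 rose from 25.7 ± 1.35 to 35.4 ± 2.05 FPKM, both also when adjusted over the list alone. Of 4 glial and neuronal markers 1 rose and 1 fell, and 2 rose and 1 fell when adjusted over the list alone. TUBB3, a neuronal tubulin, rose from 41.1 ± 1.16 to 64.2 ± 7.05 FPKM, while OLIG2 was at 3.37 ± 0.0758 and 3.39 ± 0.255 FPKM (limma adjusted p 0.98). Of 4 epithelial markers 2 rose and 1 fell, also when adjusted over the list alone, with KRT17 rising and KRT7 falling from 7.77 ± 1.02 to 4.47 ± 0.348 FPKM. The other rise was KRT8 (limma adjusted p 0.0304), with an adjusted p of 0.0845 to 0.119 without control replicate 1, 2 or 3 or knockdown replicate 2, 0.051 with no filter on low values and 0.0673 with the gene length trend removed. Below the filter, summed reads over the 3 control and the 3 knockdown-labelled libraries were 0 and 108 for KRT6A, 0 and 30 for KRT19, 0 and 9 for KRT14, 1 and 7 for EPCAM, 40 and 225 for CLDN4, and 7 and 6 for KRT5. Among endothelial and pericyte markers below the filter they were 0 and 268 for ABCC9 and 173 and 44 for CDH5, and among neuronal markers 587 and 1256 for RBFOX3 and 203 and 128 for SNAP25, which were chosen after their values were seen.

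**Figure D5:**
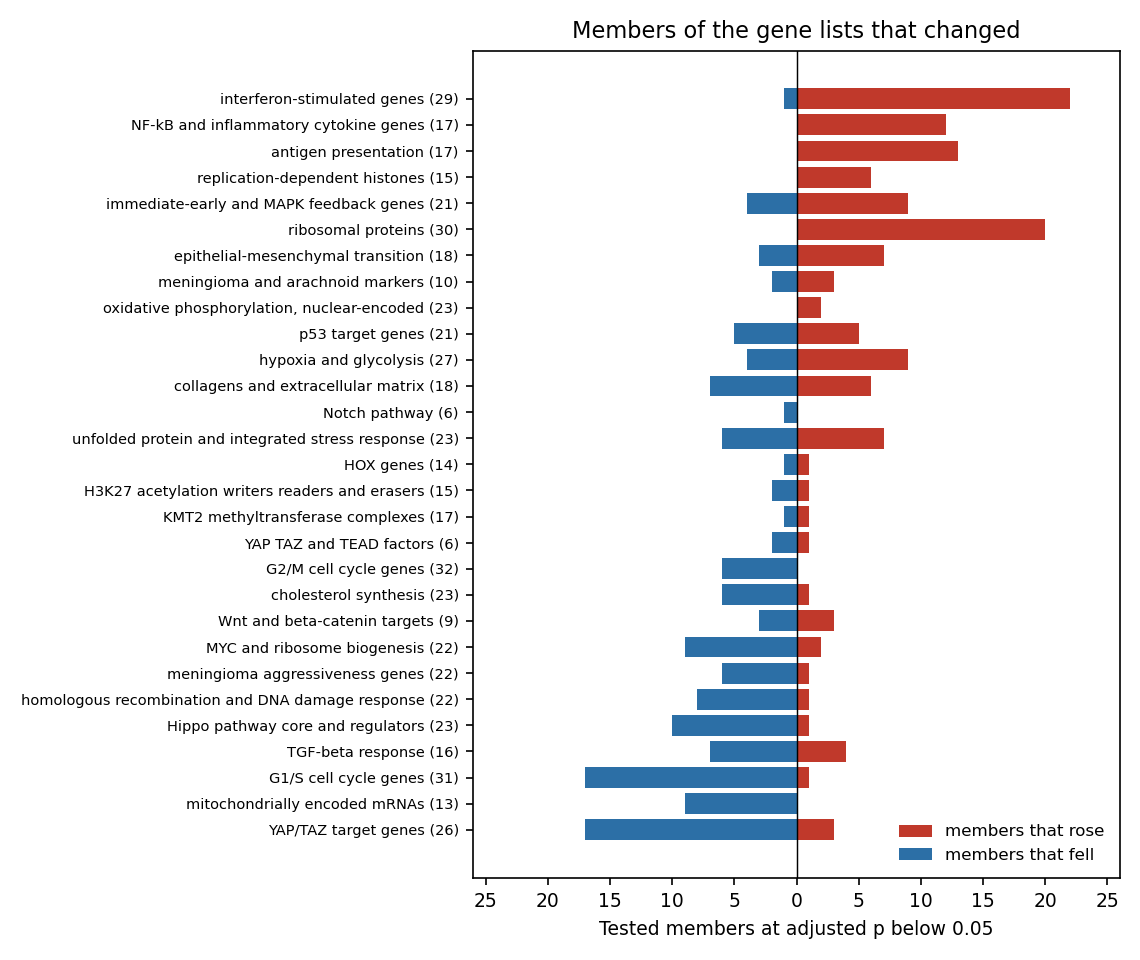
Number of tested members of each gene list (vertical axis, number tested in parentheses) that rose (red, to the right) or fell (blue, to the left) at an adjusted p below 0.05 over all tested genes. Of 29 interferon-stimulated genes 22 rose, and of 26 YAP/TAZ target genes 17 fell.

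The libraries of each group resembled each other more than those of the other group. Across genes, which are not independent replicates, Pearson correlations of log2(FPKM + 1) were 0.995 to 0.997 within the controls, 0.989 to 0.991 within the knockdown-labelled libraries and 0.959 to 0.978 between the groups. The first principal component held 75.7% of the variance and separated the groups. The knockdown-labelled libraries varied more among themselves, with a median dispersion of 0.0134 against 0.00374 in the controls. By transcript length, long genes were lower in control replicate 3, knockdown replicate 2 and knockdown replicate 3, with medians of -0.081, -0.157 and -0.15 in the longest of 5 length classes. KMT2C, at 17605 bp, is longer than 99.3% of the tested genes.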

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

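Removing the gene length or GC-content trend was chosen after seeing the data; the other settings were planned. The number of changed genes stayed within 1.5 times of 3268 in every setting, from 2196 without control replicate 1 to 4216 without knockdown replicate 1, and 3139 of the genes were also called by the authors' deposited Wald test with its p adjusted over the tested genes. With a replicate block 3671 genes passed, 3254 of them shared, although the replicate numbers did not pair the libraries (correlations of deviations 0.237, -0.031 and 0.03; only replicate 1 correlated best with its own number). The 223 genes at 2-fold became 411 when only the pseudocount was lowered to 0.1, so the main count depends on the added 1 FPKM. The count was 441 with limma-voom on the recovered reads and 431 in the authors' deposited Wald test, where the cause was not tested separately. Without 1 library it was 173 to 282. The KMT2C log2 change passed at -0.352 with the stricter filter (limma adjusted p 0.0429) and with the replicate block (0.039), at -0.609 with limma-voom (0.0225) and at -0.634 in the authors' deposited test (0.014). With a pseudocount of 0.1 it was -0.581 and did not pass (limma adjusted p 0.0949), so its size depended on the pseudocount. Without 1 library it was -0.514 to -0.237, passing only without control replicate 3, and its adjusted p over all settings reached 0.322. The cause of the differing calls was not tested. Hippo genes that fell numbered 6 with no filter and 4 to 14 without 1 library, and ribosomal protein genes that rose numbered 6 with no filter and 4 to 25 without 1 library; the cause was not tested. With a correlation estimated per list 0 lists passed, and the interferon, YAP/TAZ target and Hippo lists had adjusted p of 0.499, 0.422 and 0.623. The size of the correlation does not account for all of this loss. The immediate-early list, at an estimated correlation of 0.001 against the preset 0.01, went from a limma camera p of 0.0682 to 0.118. Before adjustment, limma camera with an estimated correlation gave p of 0.0145 for YAP/TAZ targets, 0.0369 for interferon-stimulated genes and 0.27 for Hippo genes. Lists that did not pass there are not shown to be unchanged. Fry called 13 lists, losing 4 that camera called and gaining 5. Without 1 library the Hippo list had an adjusted p of 0.0017 to 0.0506.

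Directions reversed only in results far from the threshold, and the cause was not tested. The collagen list turned down with upper-quartile factors (adjusted p 0.917), no filter (0.881), the stricter filter (0.796) and the GC-content trend removed (0.939), and had 0.625 to 0.84 without 1 library. Without 1 library the Notch list had 0.564 to 0.936, the HOX list 0.568 to 0.999 and the stress response list 0.15 to 0.954, each reversing once. OLIG2, at a log2 change near 0, was at -0.01 with the length trend removed, -0.043 with the GC-content trend removed and -0.037 to 0.047 without 1 library. Over the 146 named genes, 2186 gene and setting pairs kept direction and side of the threshold, 104 in 34 genes fell short of it, 35 in 9 genes newly passed and 4, all OLIG2, reversed. Over the lists other than the 3 above, 402 pairs kept both, 21 fell short, 10 newly passed and 9 reversed. Planned count tests with quasi-likelihood were not run. Depth limits the ratios of genes with few control reads, such as CCL4L2 on 1 read.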

Other observations

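The tests of a wrong label of control replicate 3, of counting noise alone in knockdown replicates 1 and 3 and of other contractile genes, and the interferon, MHC class II and pathway values in this part, were chosen after the result was seen. Interferon genes themselves were detected in the knockdown-labelled libraries. IFNL1, a type III interferon, had 0 control reads against 535 knockdown reads, at least 182-fold higher against a floor of 3 reads over the group. IFNB1, the type I interferon made by most cell types, had 1 control read against 158, a ratio of 161 with a counting interval of 28.5 to 6410. IFNL2 had 0 against 100 reads, at least 34-fold higher, and IFNL3 had 6 against 113, a ratio of 19.2 with an interval of 8.56 to 53.5, though IFNL2 and IFNL3 are near-identical copies. CCL3 had 0 against 436 reads, at least 148-fold higher, and CCL4 had 0 against 203, at least 69.1-fold higher. The RNA sensors DDX58 and IFIH1 rose from 5.33 ± 0.0464 to 20.9 ± 4.01 and from 1.33 ± 0.0316 to 5.98 ± 1.22 FPKM. IRF1 rose from 6.88 ± 0.602 to 16.8 ± 6.32 FPKM. Among receptor chains, IFNAR1 fell from 9.80 ± 0.650 to 6.90 ± 1.62 FPKM. IFNAR2 did not pass, at 5.68 ± 0.326 and 6 ± 0.903 FPKM (limma adjusted p 0.73). IL10RB, part of the type III receptor, rose from 9.81 ± 0.644 to 13.9 ± 1.30 FPKM. IFNLR1, the other chain of that receptor, was not among the listed genes. CIITA, the master regulator of MHC class II, had 240 control reads against 1150, a ratio of 4.89 with an interval of 4.25 to 5.65, and HLA-DPA1 rose from 0.561 ± 0.198 to 9.82 ± 2.25 FPKM.

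Of 303 KEGG pathways, limma camera called 17 up and 5 down, but 0 with an estimated correlation, where the smallest adjusted p was 0.979. Antigen processing and presentation had 20 rising and 3 falling of 40 genes (limma camera adjusted p 1.74e-06), and Ribosome had 51 rising and 7 falling of 126 (8.6e-06). Nucleocytoplasmic transport had 27 falling and 1 rising of 95 (0.00132), and DNA replication had 11 falling and 1 rising of 35 (0.0451). Hippo signaling had 28 falling and 10 rising of 97 genes, at an adjusted p of 0.107.

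KMT2C mRNA overlapped between the groups, and the variance of KMT2C reads at equal depth was 105 times their mean among the controls, but libraries differ by more than counting noise anyway, so the bound set for this ratio was no test of the overlap. On the deposited scale knockdown replicates 1 and 3 lay 3.64 and 0.739 counting errors above control replicate 3, but such gaps between single libraries decide nothing, so counting noise cannot be told apart from a real overlap. A wrong label of control replicate 3 is argued against by its correlations, the smallest with a control exceeding the largest with a knockdown-labelled library by 0.0168. With the length trend removed 2 knockdown-labelled libraries still lay at or above the lowest control, but by at most 0.792 counting errors, so fewer reads from long transcripts cannot be told apart from a real overlap at this depth.

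The rise of interferon-stimulated and chemokine genes may be a response of the cells themselves. Leukocytes in the cultures are argued against: 9 leukocyte markers other than CD68 gained 0.975 FPKM in sum (SE 0.44), where 5 were needed, and CCL5 alone gained 52.9 FPKM. Of these 9 markers 5 gained, with CD3D reaching 1.02 FPKM, LYZ 0.388, CSF1R 0.383, ITGAM 0.189 and CD79A 0.0959, and PTPRC, CD14, FCER1G and AIF1 were lower, while CD68, which the cells express at 107.5 FPKM in controls, reached 145.1 FPKM. A length or GC trend is argued against, since 24 interferon-stimulated genes still rose with both removed, and 22 to 25 without 1 library. A response to the delivered construct cannot be told apart from an effect of lower KMT2C. The labels do not say what the control cells received, and 0 further groups (another construct, an untreated culture or a rescue) separate them.

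Most YAP/TAZ target genes fell, as did 10 of 23 Hippo genes. LATS2 and AMOTL2 fell and are on both lists, so the counts are not separate. Whether the falls are linked was not tested. For the targets a length trend is argued against, since 18 still fell with it removed, and 13 to 18 without 1 library. A composition shift of the FPKM scale is argued against by a median log2 change of -0.509 under median-of-ratios scaling. For the Hippo genes 8 still fell with the length trend removed, but 4 to 10 without 1 library, against 4 to 14 with the trend left in. The list's limma camera adjusted p was 0.0434 with the trend removed and the preset correlation. With counts this dependent on single libraries, a length trend cannot be told apart from a fall of these genes. A response to the construct stays open here too.

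Of 18 other contractile and actin-cytoskeleton genes, 9 fell and 0 rose, which is exactly the share set as the bound, including TPM1 at -1.20, CALD1 at -0.48, CSRP1 at -0.44 and ACTN1 at -0.39 on the log2 scale. The other 9 did not pass, among them ACTA2 at 0.11, VCL at 0.05, TPM2 at -0.09, FHL2 at -0.02 and ZYX at -0.04, and EGR1, another gene driven by serum response factor, rose 10.9-fold. SRF, the gene of the factor itself, was among the 9 that fell, at -0.39 (limma adjusted p 0.0206). A wider fall of genes driven by serum response factor beside TAGLN and MYL9 stays an open hypothesis. The largest shift of a chromosome's median log2 change was 0.126, on chromosome 17, below the bound of 0.25 set for copy-number drift. Of the 10 splits of the 6 libraries into 3 and 3, only the real split gave 3268 changed genes (0 in the highest other split) and 223 at 2-fold (0 in the highest other). For the gene lists 3 of the 10, the real split among them, gave as many, with 12 in the real split and 13 in the highest other. Every other split mixes the labels, so a difference between the labels enters the spread within its groups. Few genes were therefore likely to pass there from the start. The splits are too few for a share under 0.05.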
